A study of Gasterosteus aculeatus with 34 samples.

How the data were processed

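RNA was measured in the telencephalon and the diencephalon of 17 male threespine sticklebacks (Gasterosteus aculeatus) of the white ecotype, which gave 34 libraries. The males were laboratory-reared offspring of wild-caught parents. Per the labels' protocols, each male went through 8 trials, every treatment being given more than once in random order, and both regions were dissected 60 minutes after the final trial. The treatment of that final trial defines the group. In the control, both flasks in the tank were empty. The courtship opportunity was a gravid female in a flask, the territorial challenge was a rival male in breeding colour in a flask, and the tradeoff presented both at once. The groups held 4 control, 4 courtship, 5 challenge and 4 tradeoff males, and each male contributed a library per region. The replicate number is the male's number in the label.

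The authors extracted RNA with a column kit, prepared stranded mRNA libraries and sequenced them on a NovaSeq instrument, per the labels' protocols. Alignment and counting used STAR and HTSeq, per the submitters' processing notes; their versions, the genome build, the annotation and the strand setting of the counting are not given in the sources used here. The deposited files hold raw read counts per gene model, not normalized, for 22295 gene models. Each file ends in 5 summary rows of HTSeq that name no gene (no feature, ambiguous, too low quality, not aligned, alignment not unique). These rows stayed out of library sizes and tests. Of all counts and summary rows in a library, no-feature reads made 38.5% ± 1.03 (SD, n = 17) in the telencephalon and 35.31% ± 1.09 (n = 17) in the diencephalon. Not-unique alignments made 19.3% ± 2.45 and 4.102% ± 0.264, and ambiguous reads 0.6312% ± 0.0313 and 1.169% ± 0.0745. Depth over gene models was 22802875 to 36656215 counts in the telencephalon and 16522465 to 34384860 in the diencephalon. Counts without molecular identifiers are not independent molecules.

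The identifiers comprise 20747 Ensembl genes, 657 gene models on chrY, 833 other models and 58 Ensembl-style genes marked as alternatives on unplaced sequence. Reads of chrY models with a near-identical copy elsewhere could be split or dropped as not unique, so their values are uncertain. None of the identifiers (0 of 22295) matched the reference table of 52177 genes for assembly fGasAcu3.hap1.1, and the files pair no names with them. The 23 gene lists fixed before the data were examined, the markers of other cell types among them, were therefore not tested, and the naming rule fixed with them, which needs symbols, could not be used. In its place, chosen after the data had been examined, the text names the 2 genes with the largest log2 fold in each direction of the region comparison with a mean of at least 1 CPM. Of the treatment comparisons it names the gene with the lowest adjusted p and 2 of the genes called in both regions under other settings.

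Pairs of libraries of one group were compared by a chi-square test of their counts. The 56 pairs had chi-square values per degree of freedom of 12.24 to 97.64, so that no pair agreed within sampling noise and every library was counted as 1 replicate.

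Tests used edgeR 4.0.16 in R 4.3.3 with TMM factors, the filterByExpr filter and the robust quasi-likelihood F test, with Benjamini-Hochberg adjustment at 0.05 over all genes of a comparison. Treatments were compared within a region in a fit of its 17 libraries. Non-additivity was the contrast of the tradeoff and control against the courtship and challenge groups (tradeoff minus courtship minus challenge plus control). Regions were compared over 34 libraries with treatment as a covariate, and differences of a treatment response between regions in a fit of all 8 groups. CPM values were computed from the counts with the TMM factors of the fit they belong to. The position of a library on the region axis is the projection of its log2 CPM on the difference of the mean profiles, with its own male left out of both means. Standard errors were the log2 fold change divided by the square root of F. Overlap of responses was measured as the correlation and covariance over genes of log2 fold changes, set beside 20 simulated sets of unchanged groups and 10000 permutations of the treatment labels. The treatment share of variance used 100000 permutations of the labels.

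The same male gave both regions, so the numbers pair the libraries. The deviations from the group means correlated between the regions of a male with a mean r of 0.355 over genes (0.0876 to 0.499 over 17 males; median of -0.0188 for different males; permutation p = 1e-05, the smallest that the permutations can give). Of the 17 telencephalon libraries, 15 correlated best with their own male.

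The pipeline was tested on simulated counts drawn from the real means, spreads and library sizes, with 200 genes changed per simulation in 5 simulations. The changed genes were spread evenly over folds of 1.5, 2, 4 and 8. Of genes changed 2-fold, it called 63.6% for the challenge against the control in the telencephalon (18277 genes) and 77.6% in the diencephalon (18399 genes). For the tradeoff against the control, it called 61.6% and 74%, and for non-additivity 49.2% and 62%. For a 1.5-fold change the challenge values were 40% and 50.8%. The simulation treats genes as independent and gives each gene a single fitted spread. The adjusted p depends on how many genes change and by how much. The shares called hold for this mix of folds, and fewer changed genes would make the threshold stricter. For the challenge against the control, 2.66% and 2.61% of the real genes had an unadjusted p under 0.05. A calibrated test without changed genes would give a larger share. The simulated shares may therefore overstate what the test could find in the real data.

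Alternatives listed before the data were examined were DESeq2 1.42.0, RLE factors, no filter, a mean count of at least 10, limma 3.58.1 voom with quality weights, a term for the range of male numbers, fits of the compared groups alone, the male as a block for the region results, split controls for the overlap, and leaving out each male. Surrogate variables (sva 3.50.0), leaving out the telencephalon libraries that stand apart, the global tests and the chrY class were added after the data had been examined. Figures were drawn with matplotlib 3.10.9.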

Results

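Gene expression was measured in the telencephalon and the diencephalon, the forebrain regions that hold much of the circuitry of social behaviour in fish, of 17 male sticklebacks. The study asks how the brain responds to an opportunity to court, to a territorial challenge, and to both at once. The control, courtship, challenge and tradeoff groups held 4, 4, 5 and 4 males. Gene models received 28101714 ± 3386758 counts per telencephalon library (SD, n = 17; 22802875 to 36656215) and 22535700 ± 4634064 per diencephalon library (n = 17; 16522465 to 34384860). A telencephalon library detected 19540 to 19930 gene models and a diencephalon library 19916 to 20325. Genes are given by identifier, since the files pair no names with them.

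The telencephalon and the diencephalon differed in most of the genes tested. Of 18923 genes, 6857 were higher and 7034 lower in the telencephalon at adjusted p under 0.05 (edgeR quasi-likelihood test), and 938 of these were higher and 1883 lower by over 2-fold. ENSGACG00000005648 was the gene with the largest rise, at 231 ± 43.9 CPM in the telencephalon and 4.26 ± 8.99 CPM in the diencephalon (SD, n = 17 each; log2 fold 6.09, SE 0.47, edgeR adjusted p = 8.3e-13). ENSGACG00000017663 was higher in the telencephalon at 4.33 ± 5.43 against 0.0555 ± 0.0625 CPM (log2 fold 6.01, SE 0.87). ENSGACG00000017661 was lower in the telencephalon, with 0.0374 ± 0.106 against 4.61 ± 1.97 CPM (log2 fold -6.78, SE 0.44, edgeR adjusted p = 2.94e-15). ENSGACG00000018030 was also lower, with 10.8 ± 38.6 against 321 ± 103 CPM (log2 fold -6.73, SE 0.74), and the telencephalon library of male 304 alone held 160.5 CPM. Without male 304, the log2 folds of these genes were 6.81, 6.36, -7.96 and -7.87 in the order given, and 13931 genes were called.

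Gene models on chrY, the male-specific chromosome of sticklebacks, leaned towards the telencephalon. Of 463 chrY models tested, 214 were higher and 94 lower there, so that 69.5% of those called were higher, against 49% of the called Ensembl genes (6545 higher and 6815 lower; Fisher's exact test, two-sided, p = 7.11e-13, over genes, which are not independent replicates). The median log2 fold of chrY models was 0.17 and that of Ensembl genes -0.02. The class was chosen after the data had been examined. Counts on chrY models made 1.479% of gene counts in the telencephalon and 1.311% in the diencephalon, and the share was higher in the telencephalon of 17 of 17 males (difference 0.1676 points ± 0.0635 SD; exact sign-flip permutation p = 1.53e-05). Other models that are not on chrY were called higher in 91 cases and lower in 113.

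The regions also differed in how their reads were accounted for. Not-unique alignments took 15.2 points ± 2.41 (SD, n = 17 males) more of a telencephalon library than of the diencephalon library of the same male, and the share assigned to genes was lower, at 41.56% against 59.42% (each in 17 of 17 males, exact sign-flip permutation p = 1.53e-05). The telencephalon library of courtship male 329 stood apart at 11.35%, the other telencephalon libraries lying between 17.17% and 21.93%. Since every male shows this difference, it cannot be separated from the region in the gene comparison.

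**Figure D1:**
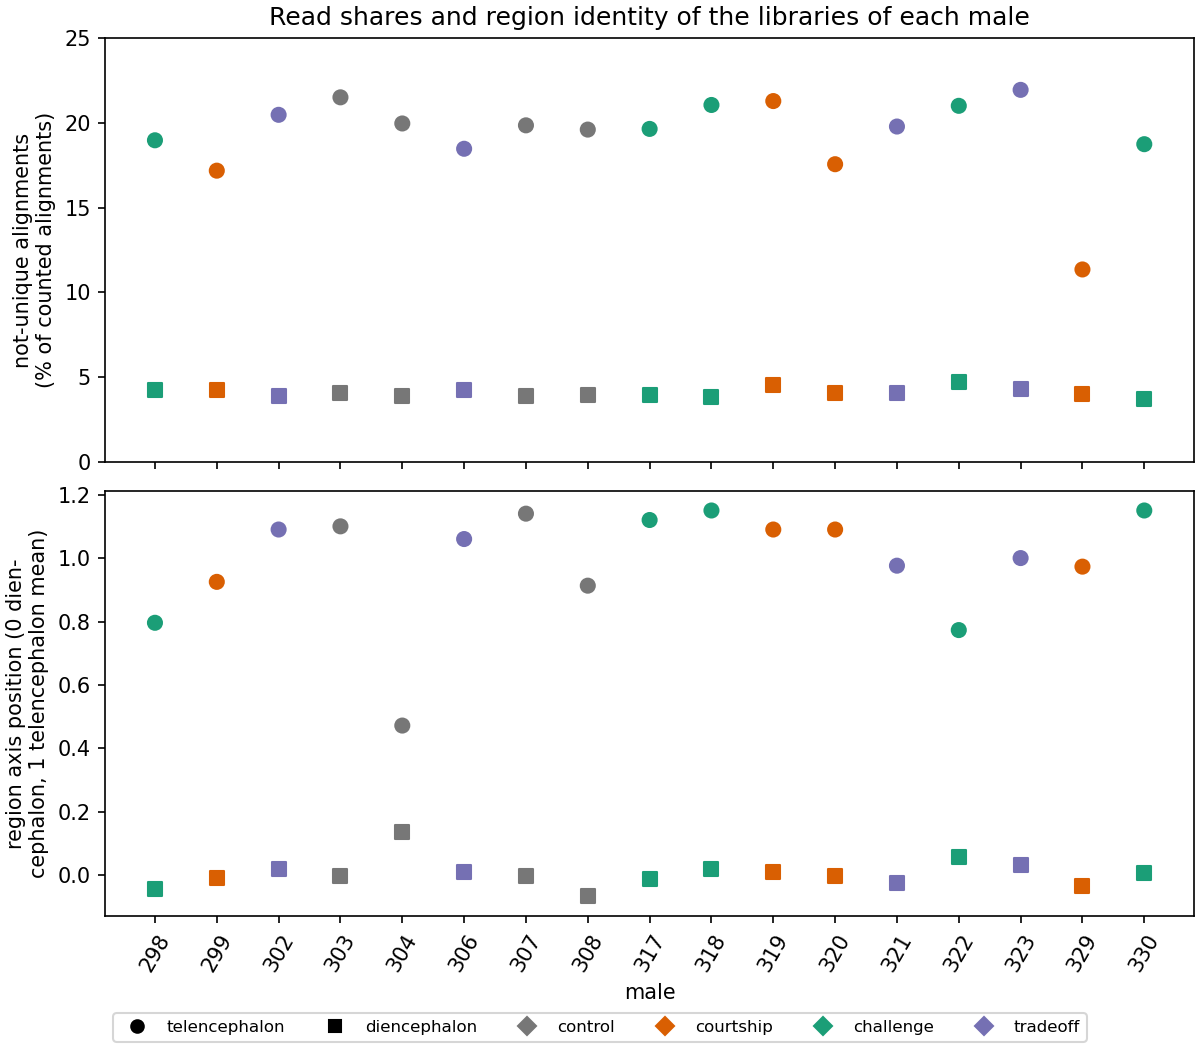
The upper plot gives the share of not-unique alignments (percent of counted alignments) and the lower plot the position of each library between the mean diencephalon (0) and the mean telencephalon (1) profile, by male, with circles for the telencephalon, squares for the diencephalon and colours for the treatment. Telencephalon shares lie between 11.35% and 21.93% and diencephalon shares between 3.724% and 4.728%, and the telencephalon library of male 304 sits at 0.472 on the region axis.

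Some libraries of a region stood apart from the rest in a few genes. ENSGACG00000009153, singled out after its values had been seen, ranged from 0 to 1360 CPM over the telencephalon libraries (median 5.67, n = 17) and from 0.526 to 3370 CPM over the diencephalon libraries (median 716, n = 17). It belongs to a set of 6 genes chosen in the same way. Without the 4 telencephalon libraries above 500 CPM of ENSGACG00000009153 (males 298, 304, 308 and 321), each telencephalon treatment comparison described below again gave 0 genes in edgeR, while the genes at an unadjusted p under 0.05 rose, for courtship against challenge from 625 to 1603. Of the controls only males 303 and 307 remained in this setting, so its 0 calls against the control rest on few libraries.

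**Figure D2:**
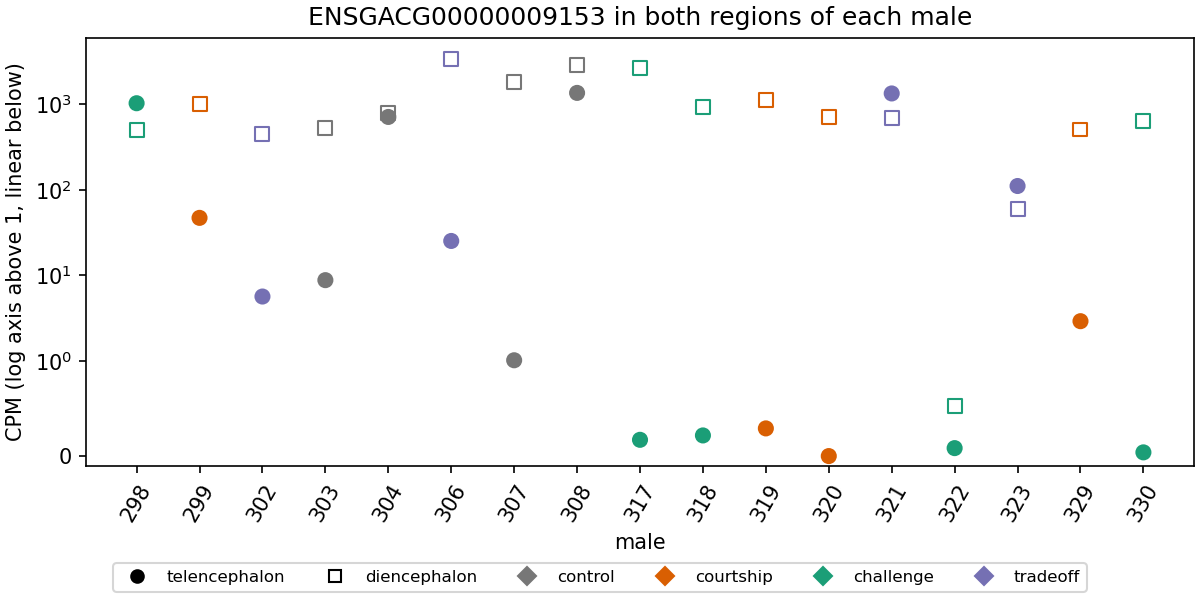
The level of ENSGACG00000009153 (CPM, log axis above 1 and linear below) is drawn for each male, with filled circles for the telencephalon, open squares for the diencephalon and colours for the treatment. Telencephalon values run from 0 to 1360 CPM and diencephalon values from 0.526 to 3370 CPM. In the telencephalon, high and low libraries occur within the control, challenge and tradeoff groups, and courtship libraries reach at most 47.1 CPM.

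A courtship opportunity was compared with the control to find genes that respond to a gravid female. In the telencephalon, 0 of 18277 genes passed adjusted p 0.05 in edgeR. DESeq2 called 1 gene and limma voom 0, and 459 genes (2.51%) had an unadjusted p under 0.05 (354 to 729 with one male left out). In the diencephalon, 0 of 18399 genes passed in edgeR and limma voom, and 430 (2.34%) had an unadjusted p under 0.05 in edgeR (402 to 613). DESeq2, which was run without the low-count filter, called 0 of 21389 genes there. Of genes with a mean of at least 1 CPM, 89.1% of 16437 in the telencephalon and 94.2% of 17014 in the diencephalon had a 95% interval that lay within 2-fold of no change.

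A territorial challenge, set against the control, likewise gave 0 genes in edgeR in either region. In the telencephalon DESeq2 called 1 gene, limma voom 0, and 486 genes had an unadjusted p under 0.05 (364 to 871 with one male left out). In the diencephalon both other tools called 0 genes and 481 had an unadjusted p under 0.05 (392 to 892). The intervals of 90.1% of telencephalon genes and 94.6% of diencephalon genes lay within 2-fold.

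The tradeoff of both stimuli gave 0 genes against the control in either region in edgeR. The telencephalon had 502 genes at an unadjusted p under 0.05 (354 to 914 with one male left out; 1 gene in DESeq2, 0 in limma voom) and the diencephalon 578 (434 to 982; 0 in both tools). Intervals within 2-fold covered 88.1% and 93.7% of genes.

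The tradeoff was next set against each stimulus alone. Against the courtship group, 0 genes passed in edgeR, with 697 genes at an unadjusted p under 0.05 in the telencephalon and 830 in the diencephalon, the highest count of each region among the pairwise comparisons in the main fit, though not under every setting. DESeq2 called 5 and 4 genes and limma voom 0 and 0. With only the compared groups in the edgeR fit, 4 genes passed in the telencephalon and 8 in the diencephalon. ENSGACG00000010779, chosen after its values had been seen, was called in each region by DESeq2 and by the fit of the compared groups. In the telencephalon it was at 11.8 ± 0.941 CPM after courtship and 26.1 ± 1.94 CPM after the tradeoff (SD, n = 4 each). In the diencephalon the values were 10.5 ± 1.01 and 23.9 ± 2.71 CPM, on the scale of all 34 libraries. On the same scale, control and challenge males ranged from 11.7 to 23.2 and from 9.83 to 24.7 CPM in the telencephalon (n = 4 and 5). In the diencephalon they ranged from 9.83 to 25.3 and from 10.5 to 21.2 CPM. The level of this gene followed the male between the regions, with an r of 0.934 after subtraction of the group means. Against the challenge group, 0 genes passed in edgeR, with 629 and 650 genes at an unadjusted p under 0.05, 2 and 1 genes in DESeq2 and 0 in limma voom in both regions. The courtship and challenge groups also differed in 0 genes in edgeR (625 and 724 at an unadjusted p under 0.05, and 1443 and 1210 without male 298; 2 and 2 in DESeq2, 0 in limma voom).

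ENSGACG00000017870 was the gene that other settings called in both regions between the courtship and challenge groups, and it was chosen after its values had been seen. It was at 4.84 ± 0.92 CPM after courtship (SD, n = 4) and 0.346 ± 0.274 CPM after challenge (n = 5) in the telencephalon (log2 fold 3.81, SE 0.9, edgeR adjusted p = 1). In the diencephalon the values were 7.6 ± 0.543 and 0.736 ± 0.181 CPM (log2 fold 3.36, SE 0.7, edgeR adjusted p = 0.999). Over the alternatives its adjusted p ran from 0.0131 (DESeq2) to 1 in the telencephalon and from 1.37e-05 (edgeR fit of the compared groups alone) to 1 in the diencephalon, with 2 settings past 0.05 in each region. The control and tradeoff groups, at 2.8 ± 2.52 and 1.47 ± 2.19 CPM in the telencephalon (n = 4 each), held low and high males. On the scale of all 34 libraries, every telencephalon library was at 0.17 to 0.836 or at 4.04 to 6.32 CPM and every diencephalon library at 0.445 to 1.14 or at 6.2 to 7.72 CPM. The level of the gene in a male followed between the regions, with an r of 0.882 over 17 males after subtraction of the group means.

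Whether the tradeoff differed from the sum of both single responses was tested as non-additivity. In the diencephalon ENSGACG00000007675 had the lowest adjusted p of all treatment comparisons, 0.499 in edgeR (log2 value -1.39, SE 0.25). It was at 6.92 ± 1.22 CPM in controls, 10.4 ± 2 after courtship, 10.7 ± 2.36 after challenge and 6.14 ± 0.388 after the tradeoff (SD; n = 4, 4, 5 and 4). DESeq2 called it, at adjusted p = 0.0034, and edgeR called it without challenge male 298, at adjusted p = 0.041; over 24 alternatives the adjusted p ran from 0.0034 to 1, with 2 past 0.05. In the telencephalon the same gene was at 2.76 ± 1.32, 3.17 ± 1.08, 2.87 ± 1.64 and 2.9 ± 1.33 CPM in the same order of groups, on the scale of all 34 libraries. Over all genes, 0 passed in edgeR in either region (545 in the telencephalon and 509 in the diencephalon at an unadjusted p under 0.05), 2 and 2 in DESeq2 and 0 in limma voom.

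**Figure D3:**
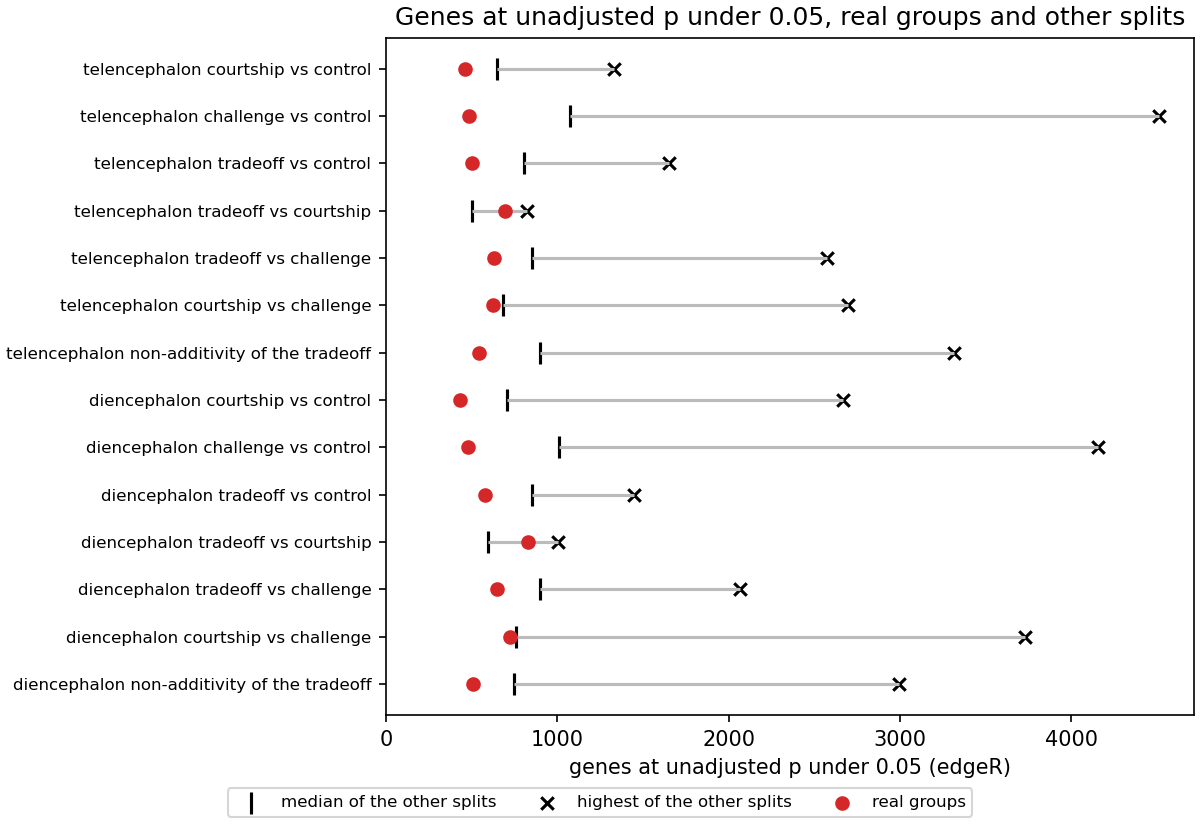
The number of genes at an unadjusted p under 0.05 (edgeR, horizontal axis) is drawn for each treatment comparison, with the real groups as red points, the median of other splits of the same males as a bar and their highest value as a cross. In the tradeoff against courtship comparisons the real groups gave 697 and 830 genes, with medians of 501.5 and 598.5 for other splits and highest values of 824 and 1007.

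Treatment as a whole took 17% of the variance of log2 CPM in the telencephalon and 17.2% in the diencephalon. Permuted labels gave a median of 18.5% in both regions (permutation test, one-sided, p = 0.752 and 0.782). Of the 12 pairs of groups, the courtship and tradeoff males lay farthest apart in the telencephalon, with a root mean square difference of 0.353 on the log2 scale and a median of 0.314 for other splits (exact permutation p = 0.143, 5 of 35 splits with the real one included; Benjamini-Hochberg adjusted 0.858 over 12 pairs). In the diencephalon the same pair gave 0.265 against 0.241 (exact permutation p = 0.143).

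The responses to the separate treatments were compared with one another. As edgeR called 0 genes in each, 0 calls were shared. Log2 fold changes against the shared controls correlated over genes with r = 0.43 for courtship and challenge, 0.313 for courtship and tradeoff and 0.402 for challenge and tradeoff in the telencephalon. Simulated unchanged groups, in which the controls too were drawn from the control means and genes were independent, gave 0.532, 0.503 and 0.529. Permuted labels gave medians of 0.532, 0.503 and 0.534 (SD 0.109, 0.114 and 0.11). In the diencephalon the values were 0.305, 0.3 and 0.487 beside simulated values of 0.528, 0.503 and 0.525. Medians over permuted labels there were 0.53, 0.505 and 0.532 (SD 0.0922, 0.0969 and 0.0927). The covariances were below the simulated ones in each case, such as 0.0368 against 0.0577 for courtship and challenge in the telencephalon and 0.0145 against 0.031 in the diencephalon. With the controls split so that each comparison had its own 2 control males, the correlations lay between -0.238 and -0.112, where simulated unchanged groups gave -0.00337 to 0.00366 and permuted labels medians of -0.0117 to -0.00728 (lowest permutation p = 0.0463, Benjamini-Hochberg adjusted 0.111 over 6 pairs). Changes that share no library gave r = -0.0879 (tradeoff minus challenge against courtship minus control) and -0.0113 (tradeoff minus courtship against challenge minus control) in the telencephalon, and 0.00997 and 0.177 in the diencephalon. The lowest permutation p of the 10 correlations without split controls was 0.0188, for courtship and challenge in the diencephalon (Benjamini-Hochberg adjusted 0.188).

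Whether a response differed between the regions was tested by an interaction. In edgeR 0 of 18923 genes passed for the courtship, challenge and tradeoff responses, with 423, 327 and 386 genes at an unadjusted p under 0.05 (287 to 550, 272 to 473 and 205 to 582 with one male left out). DESeq2 called 1, 11 and 1 genes. The single courtship and tradeoff calls had log2 values of -21.79 and -23.15. All 11 challenge calls were negative. Among them was ENSGACG00000018030 (log2 value -5.78), which stood at 160.5 CPM in the telencephalon of control male 304 and at 0.7383 to 4.561 CPM in the other controls. With the male as a block, edgeR called 0 genes for each response, and 696, 535 and 605 genes had an unadjusted p under 0.05.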

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

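The tests of patterns in this part were chosen after the patterns were seen, and the splits of the samples were counted on unadjusted p-values after it was known that no gene passed in edgeR. Only the tests of the regression on read shares and of the region-specific genes of male 304 were set before their values were computed. Values far from the rest of their group were searched in 111 sets of a measure in a group of 4 or 5 libraries, and 14 were found. Chance gives about 1 in 20 for measures chosen without regard to such values. Some of the genes searched were chosen after their values had been seen or lay near the floor. The number found can therefore not be read as an excess over chance.

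Both libraries of control male 304 lay between the regions. ENSGACG00000018030, a diencephalon gene, was at 160.5 CPM in its telencephalon library and at 0.7383 to 4.561 CPM in the other controls, and ENSGACG00000005648, a telencephalon gene, was at 38.67 CPM in its diencephalon library against 0.4345 to 3.678 CPM. On an axis from the mean diencephalon (0) to the mean telencephalon (1), its telencephalon library lay at 0.472, the next lowest being 0.773, and its diencephalon library at 0.137, above the range of -0.0662 to 0.057 of the others. Swapped region labels are excluded by the position of 0.472, and the control treatment by the other control libraries, the lowest of which lay at 0.913, within the 0.773 to 1.15 of the other treatments. Tissue or RNA of each region in the library of the other may be the source. Of 117 diencephalon-specific genes 74.4% were highest in the telencephalon library of male 304, against at most 12% for another male. Of 19 telencephalon-specific genes 73.7% were highest in its diencephalon library, against at most 15.8% for another male. In its telencephalon library the diencephalon-specific genes rose by a median of 50.5% of their diencephalon level (quartiles 39.8% and 59.9%). In its diencephalon library the telencephalon-specific genes rose by a median of 16.1% of their telencephalon level (12.6% and 18.8%). Both shares of highest genes fell short of the 80% set in advance, so by that rule this stays open.

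A group of 6 genes was near absent from most telencephalon libraries and abundant in some. ENSGACG00000009153 was at 1035 CPM in challenge male 298 and at most 0.2166 CPM in the other challenge males, at 1341 CPM in tradeoff male 321 (5.668 to 111.3 CPM in the others) and at 47.07 CPM in courtship male 299 (at most 2.918 CPM). Diencephalon tissue as a whole is excluded as the sole source of the 6 genes in males 298, 308, 321 and 323. In them the upper quartile of 140 other diencephalon-enriched genes rose by at most 0.129 (male 323) of the median share that the 6 genes reached. In male 298 that upper quartile stood at 25.7%, above the baseline of 15%, so some diencephalon tissue is not excluded there. In male 323 that upper quartile stood at 16.7% of the diencephalon level, where such tissue would give 28.2% and the libraries without the 6 genes reached 19.5%, except for 54.4% in male 322. The 28.2% rests on the median level over all diencephalon libraries. The diencephalon of male 323 itself held the 6 genes at 2.83 to 59.2 CPM, and its telencephalon at 5.92 to 111 CPM. This test replaced, after its result was seen, a ratio with no baseline taken off that did not exclude the tissue (lowest 0.793 over 5 libraries, in male 323), and male 323 was added to it later. Male 304 (0.746) stays open. Not all of the 6 genes rose in each library: 2 of them were at 0.238 and 3.74 CPM in the telencephalon of male 308 (253 and 1140 CPM in its diencephalon), and 1 was at 0.246 CPM in that of male 321 (428 CPM). A piece of tissue that is present in varying amount in either dissection therefore stays open. The 6 genes also varied together over the diencephalon libraries (median Spearman rho 0.549, highest of 1000 shuffles 0.252). The pick had used these libraries only through their median, which had to exceed that of the telencephalon. But the same piece in each library would bring all of the 6 genes. The treatment of the final trial stays open as well (permutation p = 0.198 over 17 males).

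Genes whose level follows the male in both regions were a small share of all genes, 2.16%, but more than re-paired males gave. After subtraction of group means, 409 of 18923 genes had an r over 0.9 between the regions, while re-paired males gave at most 2 in 100 re-pairings. Models on chrY made 2.69% of them, which excludes chrY as the whole cause. They were 11 of the 409, and 463 of the 18923 genes tested were chrY models (Fisher's exact test over genes, p = 0.745). Of the 409 genes, 96 had a range over 4 on the log2 scale. In the males with such a gene on, the regions differed by a median of 0.458 on that scale. RNA carried between libraries would leave one region far below the other. Read shares of the libraries cannot be told apart as a cause: regression on them left 62 genes, but shuffled shares left a median of 66. Differences between the males themselves, such as inherited ones, may contribute and were not tested.

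In ENSGACG00000017870 (r = 0.882 between the regions), tradeoff male 302 stood apart in both regions, with 5.089 CPM in the telencephalon (0.1716 to 0.6141 in the other tradeoff males) and 6.228 CPM in the diencephalon (0.7711 to 1.081). Challenge male 322 had 5.723 CPM of ENSGACG00000007675 in the telencephalon (1.653 to 2.741 in the others) and 0.1752 CPM of ENSGACG00000017663 in the diencephalon (at most 0.03993). Courtship male 319 had 2.803 CPM of ENSGACG00000005648 in the diencephalon (0.4795 to 0.573). ENSGACG00000017661 was near its floor in the telencephalon, with 0.1164 CPM in courtship male 319, 0.04291 CPM in tradeoff male 323 and 0.43 CPM in control male 304. The telencephalon library of tradeoff male 306 held 30682988 gene counts, against 25242313 to 25426404 in the other tradeoff males.

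Other splits of the same males gave as many genes at an unadjusted p under 0.05 as the real groups in each treatment comparison, so chance could not be excluded for any of them. The counts that follow include the real split. In the telencephalon, 34 of 35 splits gave as many for courtship against control (459 genes, highest other 1333), 90 of 100 for challenge against control (486, 4510), 34 of 35 for tradeoff against control (502, 1653), 6 of 35 for tradeoff against courtship (697, 824), 79 of 100 for tradeoff against challenge (629, 2577), 55 of 100 for courtship against challenge (625, 2694) and 85 of 100 for non-additivity (545, 3314). In the diencephalon the counts were 32 of 35 (430, 2667), 96 of 100 (481, 4158), 29 of 35 (578, 1448), 6 of 35 (830, 1007), 82 of 100 (650, 2064), 54 of 100 (724, 3728) and 86 of 100 (509, 2994) in the same order. For the region differences in the courtship, challenge and tradeoff responses, 49, 66 and 55 of 100 assignments of treatments to males gave as many (423, 327 and 386 genes; highest others 1777, 1775 and 1779), and with the male as a block 56, 75 and 66 of 100 did (696, 535 and 605; highest others 2889, 2797 and 2739). Why some splits gave several times the real count was not tested. For the regions, chance was excluded: 1 of 100 assignments, the real one, gave 13891 calls, and the highest other, in which 3 males were swapped, gave 9908.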

How the results depend on the processing

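Surrogate variables, the leaving out of libraries that stand apart, the global tests and the chrY class were chosen after the data had been examined. With the male as a replicate block, the region comparison called 15036 genes (13829 of the 13891 called without it, all in the same direction, and none in the opposite one). Of chrY models, 226 were then higher and 102 lower in the telencephalon, against 214 and 94 without the block. The counts of 0 for the region differences in response held with the block. Region calls lay between 13705 and 14413 under the other settings, and calls of chrY models higher in the telencephalon between 202 and 230. The counts of 0 in the treatment comparisons within a region also held with RLE factors, without a low-count filter, with a mean count of at least 10, with limma voom and with the male-number term. In the telencephalon they held without males 298, 304, 308 and 321 too, which left only control males 303 and 307. For the region differences in response only RLE factors and no filter were run of these settings, and the 0 held. The cause of the changes below was not tested.

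DESeq2 called, in the telencephalon, 1 gene each for courtship, challenge and tradeoff against control, 5 for tradeoff against courtship, 2 for tradeoff against challenge, 2 for courtship against challenge and 2 for non-additivity. In the diencephalon it called 4, 1, 2 and 2 genes in the last 4 of these, and for the region differences 1 (courtship), 11 (challenge) and 1 (tradeoff). Of its 23 calls within a region, made without the low-count filter, 9 had a log2 fold over 15 in size. Fits of only the compared groups called 4 and 8 genes for tradeoff against courtship (telencephalon, diencephalon) and 1 and 1 for courtship against challenge. Surrogate variables gave 1 gene for telencephalon tradeoff against courtship. Leaving out one male gave 0 to 1 genes for diencephalon non-additivity (1 without challenge male 298) and 0 to 1 for the region difference in the challenge response (1 without male 307), and 0 elsewhere. It moved the count at an unadjusted p under 0.05 by over 1.5 times in 8 of 17 treatment comparisons, such as courtship against challenge (518 to 1443 in the telencephalon and 512 to 1210 in the diencephalon); the report gives the ranges of the others. Without telencephalon libraries 298, 304, 308 and 321 together, this count was 968 for courtship, 537 for challenge and 536 for tradeoff against control, 1214 for tradeoff against courtship, 915 for tradeoff against challenge, 1603 for courtship against challenge and 865 for non-additivity. With surrogate variables it moved by over 1.5 times in the telencephalon for courtship (702) and challenge (1219) against control, tradeoff against challenge (1636) and non-additivity (1524), and in the diencephalon for courtship against challenge (411). With limma voom it moved as far in the telencephalon for tradeoff against courtship (1179) and courtship against challenge (1149), and in the diencephalon for challenge against control (313) and tradeoff against courtship (1317). The other splits of the males were not counted again under these settings.

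With split controls, the correlations of responses became -0.196 (courtship and challenge), -0.238 (courtship and tradeoff) and -0.206 (challenge and tradeoff) in the telencephalon, and -0.225, -0.217 and -0.112 in the diencephalon. Splitting removes the shared controls by construction, which takes the value expected without a response to about 0 and does not explain the negative sign, whose origin was not tested. No-change values for this design were added after the data had been examined. Treatment shares of variance stayed between 16.96% and 21.53% and the same-male correlation between 0.3095 and 0.3766. The gene lists and their alternatives were not run, since no identifier had a name. Depth limits the region-specific genes near 0 CPM.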

Other observations

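The tests in this part were chosen after the data had been examined, except for the slope on the region axis. Of 21 genes that any other setting called in a treatment comparison, 5 (23.8%) had an r over 0.9 between the regions of a male and 10 (47.6%) an r over 0.8, against 2.16% and 6.99% of all genes (median 0.769 against 0.375; the difference was not tested), and 6 were called in both regions. The regions come from the same males, so a call in both is not independent evidence.

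The 6 variable telencephalon genes were higher on average in the males with lower numbers, by a margin at the edge of an unadjusted 0.05. Their mean log2 CPM was 3.69 ± 3.3 (SD, n = 8) in males 298 to 308 and -0.12 ± 3.91 (n = 9) in males 317 to 330, a difference of 3.81 (exact permutation p = 0.0497, two-sided, over 24310 assignments, not adjusted). The range of numbers is not named as a batch in the labels, and all control males lie in the lower range.

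Over the 17 telencephalon libraries, the position on the region axis was not seen to follow the share of not-unique alignments (Pearson r = 0.038, permutation p = 0.873; Spearman rho = 0.191, permutation p = 0.461; r = -0.0162 without the 2 libraries farthest from the median share). A slope of 1 had been set in advance as the value to expect if the share made the whole region difference. The slope over the 17 libraries was 0.0416 (95% interval -0.56 to 0.643), and this interval leaves out 1. It leans on the 2 libraries farthest from the median share. The farthest, of courtship male 329, had a share of 11.35% and lay at 0.973 on the axis. Without these 2 libraries the interval ran from -1.42 to 1.35, which holds 1, so this stays open. The read shares were set aside as a pattern to weigh after these values had been seen, and male 304 took their place. The telencephalon libraries of challenge males 322 and 298 lay at 0.773 and 0.796 on that axis, the lowest after male 304. In the telencephalon library of male 322 the upper quartile of other diencephalon-enriched genes stood at 0.544 of their diencephalon median, near the 0.654 of male 304 and above the 0.257 of male 298, and the 6 variable genes were near absent (median share 9.03e-05). These genes were also low in its own diencephalon library (0.175 to 10.2 CPM), so that their absence says nothing about diencephalon tissue of this male. That library lay at 0.057, the highest after male 304. The source of this was not tested.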
